A study of Mus musculus with 16 samples.

How the data were processed

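PolyA RNA was sequenced from the right-hemisphere cortex of newborn (P0) and 7-day-old (P7) mice. Per the labels, cortex came from control mice and from mice with a conditional knockout (cKO) of the transcription factor gene Foxp1 in the forebrain. Each of the 4 groups held 4 libraries, 16 in all, and each library was 1 replicate. The P0 libraries were sequenced on a BGISEQ-500 instrument and the P7 libraries on an Illumina NextSeq instrument, by different centres, so that age and sequencing platform were the same split of the samples.

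The deposited table held CPM values, which are read counts that the authors scaled to a common library total, for 20841 genes in 16 libraries. The submitters' processing notes name STAR, HTSeq and edgeR and the genome builds mm10 and GRCm38. The versions and settings of these tools and their order are not given in the sources used here. Within each library 100% of the values were whole multiples of the CPM of 1 read, to within 0.01 read, so the read totals could be recovered. Recovered library totals ran from 17957490 to 18232943 reads at P0 and from 9858296 to 15335738 reads at P7. The genes of the table held 95.9% to 96.6% of each total, so genes were taken out after the division by the total. No gene of chromosome X or Y was in the table, and 2859 genes were at 0 in every library. The 13 mitochondrially encoded genes were listed at 0 in every library. A count of 0 in a library allows up to 3 reads, which is 0.165 to 0.167 CPM at P0 and 0.196 to 0.304 CPM at P7. Such limits cover counting error only, since the reads carried no molecular identifiers. Between replicates of a group the chi-square per gene ran from 2.68 to 39.4, so the spread between libraries exceeded counting error, most of all among the P0 controls.

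Each age was fitted on its own, over 8 libraries, with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with eBayes moderation and a trend of the spread with abundance. A gene entered a fit with at least 1 CPM in at least 4 libraries of that fit. The difference between the genotype effects at P7 and P0 (the interaction) and the difference between P7 and P0 controls (the age effect) came from 1 fit over all 16 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The added 1 CPM makes the log2 fold changes of genes with few reads smaller than the ratios of their mean CPM. The Foxp1 level was also compared between genotypes by an exact two-sided permutation test over the 70 assignments of the 8 libraries of an age. Calls shared by both ages were counted per direction with a two-sided Fisher's exact test.

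Before the data were examined, 28 lists of genes were fixed for layers and types of cortical neurons, progenitors, glia, vessels, blood, neighbouring brain regions, synapses, channels, guidance, disease risk and stress. They were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists with at least 4 tested members. The number of such lists was 25 at each age. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. The genes named in the text followed a rule fixed at the same time. The rule took Foxp1. For each age it took the 10 genes with the largest fold changes in each direction among called genes whose 4 cKO values all lay above or all below the 4 control values. For the interaction it took the 5 largest called contrasts in each direction, and for age the 5 largest in each direction among genes with a mean of at least 10 CPM in control cortex. For each list that the text describes it took up to 4 members with the smallest p. Genes outside this rule are named as chosen after their values were seen.

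Positions come from GENCODE M21 (GRCm38), which may differ from the annotation the authors counted on. By symbol, 20374 genes of the table were matched, another 357 by an older symbol, and 110 were not matched. Of the genes, 16352 overlapped the body of no other gene of the table. For each named gene, the share of its 50-base stretches that other genes also hold was computed. No gene was left out for overlap or shared sequence.

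Alternatives fixed at the same time as the lists were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 CPM, scaling by medians of ratios, quantile normalization, a robust spread, array weights, an adjusted p under 0.1, a minimum absolute log2 fold change of 0.3, 1 fit over all 16 libraries, and leaving out each replicate in turn. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, the striatal marker level as a covariate, the exact permutation test of that level between genotypes, leaving out P0 control libraries 2 and 6 together, and genes without overlap only. After the data were seen, 8 more lists were written, and for these only counts of members are given. In place of the 32 genes called at P0 by limma, edgeR called 30 and DESeq2 called 429. At P7 limma called 477, edgeR 463 and DESeq2 604. For the interaction they called 101, 103 and 285.

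The fits were tested on simulated data in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. A further list of 20 genes was raised by 1.5-fold. Its genes count among the total calls below, but neither among the recovered genes nor among the false calls. The changed genes had a mean of at least 5 CPM, and each gene was drawn independently. Variation that many genes share within a library was thus not simulated, and the real fits may recover fewer genes and make more false calls. Of the genes changed 2-fold, 94.0% were recovered at P0, 100% at P7, 83.6% for the interaction and 98.5% for age. Of those changed 1.5-fold, 55.2%, 89.6%, 32.8% and 76.1% were recovered, and every gene changed 4-fold was recovered. False calls were 8 of 184 at P0, 12 of 221 at P7, 10 of 162 for the interaction and 6 of 205 for age. Counts in the other splits of the libraries into groups of the same sizes stand in the closing section. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.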

Results

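Foxp1 encodes a forkhead transcription factor, and cortex with and without forebrain deletion of it was profiled at birth (P0) and a week later (P7). The 4 groups were P0 control, P0 cKO, P7 control and P7 cKO, with 4 libraries each. Recovered read totals were 17957490 to 18232943 per P0 library and 9858296 to 15335738 per P7 library. At P0 the first principal component held 46.5% of the variance and set apart control libraries 2 and 6, at 38.1 and 19.5, from the other 6 libraries, which lay between -17.9 and -0.443. At P7 the first component held 25.7% and separated the genotypes, with controls from -13.3 to -6.95 and cKO libraries from 6.34 to 12.1. No count of reads over the deleted part of Foxp1 was made, because the table gives 1 value per gene.

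The first question was how far the targeted gene itself fell. Foxp1 (chromosome 6, 98925338 to 99522721, minus strand, GRCm38) had 273, 326, 340 and 364 CPM in the P0 control libraries 1, 2, 5 and 6, and 131, 166, 163 and 182 CPM in the P0 cKO libraries 3, 4, 7 and 8. At P7 it had 539, 375, 399 and 462 CPM in control libraries 43, 45, 46 and 47, and 246, 219.9, 162 and 241 CPM in cKO libraries 41, 42, 44 and 48. The mean fell from 326 ± 38.3 to 161 ± 21.3 CPM at P0 (SD, n = 4 per group, exact permutation p = 0.0286) and from 444 ± 73.3 to 217 ± 38.4 CPM at P7 (SD, n = 4 per group, exact permutation p = 0.0286). That p is the smallest that 70 assignments allow. The cKO level was 49.3% of the control level at P0 and 48.9% at P7. In limma the log2 fold change was -1.02 (SE 0.11, adjusted p = 0.00226) at P0 and -1.03 (SE 0.12, adjusted p = 0.000164) at P7. The table gives 1 value for the gene, and the predicted gene Gm20696 overlaps 44.4% of the Foxp1 body on the same strand. Of 315 genes wholly under a same-strand gene, 96.8% were listed at 0 in all P0 libraries and 97.1% in all P7 libraries. Reads from the shared part of Foxp1 may thus not have been counted, and the value may cover only part of the gene. The paralogs Foxp2 and Foxp4 did not pass at either age, with adjusted p = 0.332 and 0.401 at P0 and 0.993 and 0.680 at P7.

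**Figure D1:**
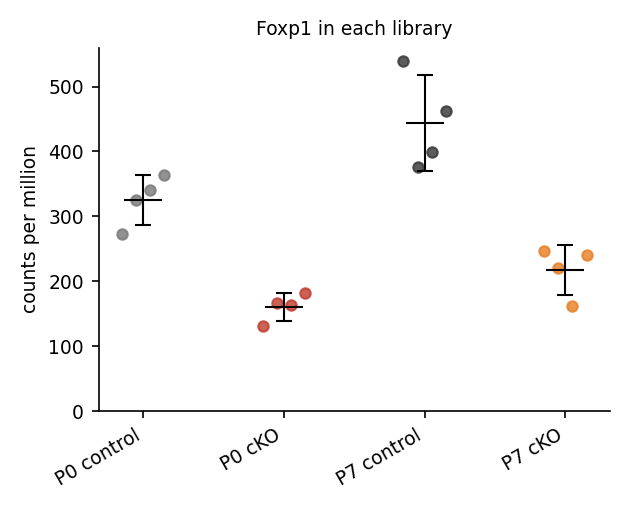
Foxp1 level in CPM (vertical axis, from 0) in each of the 16 libraries, by age and genotype, with the mean and SD of each group. All cKO libraries lie between 131 and 246 CPM and all control libraries between 273 and 539 CPM.

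The P0 comparison asks which transcripts depend on Foxp1 in newborn cortex. The retinaldehyde dehydrogenase Aldh1a3, which makes retinoic acid (chromosome 7, 66390890 to 66427517), rose from 2.27 ± 0.530 to 11.01 ± 0.841 CPM (SD, n = 4, limma adjusted p = 0.000226), a log2 fold change of 1.89 (SE 0.16). Met, the receptor of hepatocyte growth factor (chromosome 6, 17463800 to 17573980), rose from 41.8 ± 17.0 to 97.6 ± 9.79 CPM, by 1.29 on the log2 scale (SE 0.23). The somatostatin receptor gene Sstr1 (chromosome 12, 58211772 to 58214444) rose from 10.98 ± 2.51 to 26.0 ± 1.62 CPM, and the growth factor gene Fgf10 (chromosome 13, 118669791 to 118792115) from 8.39 ± 1.03 to 17.8 ± 2.28 CPM. Il1rap, a co-receptor of interleukin-1 (chromosome 16, 26581704 to 26730117), fell from 35.4 ± 8.49 to 15.7 ± 2.28 CPM, a log2 fold change of -1.11 (SE 0.16). The GTPase gene Rnd3, known for a part in the migration of new cortical neurons (chromosome 2, 51130438 to 51149111), fell from 99.1 ± 0.677 to 61.8 ± 11.1 CPM, a log2 fold change of -0.69 (SE 0.12). Lacc1, Glis3, Ccdc85a, Synpo2 and the predicted gene Gm19410 rose by 1.46, 1.04, 1.07, 1.0 and 1.26 on the log2 scale. Tshz2, a zinc finger gene of deep-layer neurons, rose by 1.21 with 65.6% of its 50-base stretches shared with other genes, so that its reads are uncertain. The metalloproteinase gene Adamts20, the formin gene Diaph3, the linker histone gene Hist1h1c and the cytokine receptor gene Lifr fell, with log2 fold changes of -1.05, -1.03, -1.03 and -0.73. Stac2 and Thsd4 fell as well, at -0.87 and -0.84. In each gene of this paragraph the 4 cKO values lay beyond all 4 control values.

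Of the 12580 genes tested at P0, limma called 32, of which 23 rose and 9 fell, and 15 changed over 2-fold. The split of higher and lower genes moved with the setting, to 65 higher and 59 lower with array weights, 62 and 74 without control library 5 and 182 and 247 with DESeq2. At an unadjusted p under 0.05 there were 2276 genes. The median SE of a log2 fold change was 0.137. The count was 794 in 1 fit over all 16 libraries and 7 with no filter. It rested on single libraries as well. It was 97 without control library 1, 136 without control library 5, 4 without cKO library 3, 9 without cKO library 4, 13 without cKO library 7 and 4 without cKO library 8, while without control libraries 2 and 6 together it was 118. Foxp1, Aldh1a3 and Lacc1 kept their calls under every alternative that tested them, which for Foxp1 and Lacc1 leaves out the fit of genes without overlap, and the other 19 of the 22 called genes named here lost theirs under at least 1. Those 19 calls were all lost without cKO library 3 and without cKO library 8, and 14 of them without cKO library 4, 11 without cKO library 7 and 8 without control library 6. With no filter 16 were lost, with quantile normalization and with edgeR 2 each, and with medians of ratios 1.

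Among the lists, the 22 tested cell cycle genes had a median log2 fold change of -0.27 at P0 (camera adjusted p = 1.7e-05, adjusted p = 0.583 with an estimated correlation). None of these passed over all genes, and 8 were lower when adjusted over the list alone. Aurkb, Mki67 and Cdk1, which act in dividing cells, had log2 fold changes of -0.66, -0.46 and -0.53. Genes of intermediate progenitors and new neurons had a median of -0.29 over 13 members, with 0 passing over all genes and 7 lower adjusted over the list alone (camera adjusted p = 0.000949, adjusted p = 0.583 with an estimated correlation). Eomes, the marker of intermediate progenitors, had a log2 fold change of -0.69, Neurod2 of -0.22, Mfap4 of -0.57 and Sox4 of -0.29, the last with 54.1% of its 50-base stretches shared with other genes. Synaptic genes had a median of 0.18 over 33 members, with 0 passing and 8 higher adjusted over the list alone (camera adjusted p = 0.0121, adjusted p = 0.583 with an estimated correlation). The receptor subunit genes Gabra2, Grin3a, Grin1 and Grin2b had log2 fold changes of 0.83, 0.63, 0.42 and 0.38. Striatal markers, expressed below the cortex, had a median of -0.36 over 15 members at P0, with 0 passing and 2 lower adjusted over the list alone (camera adjusted p = 0.000949, adjusted p = 0.583 with an estimated correlation). Their mean log2 level was 3.77 ± 0.33 in cKO and 4.22 ± 0.61 in control cortex (SD, n = 4, exact permutation p = 0.257), where control library 2 was at 3.33 and the other controls at 4.34 to 4.61. With that level as a covariate the list's adjusted p was 0.774, which decides nothing, because the covariate is the mean of the list's own members. Fry kept 0 of the P0 lists.

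Of 12 astrocyte genes at P0 1 rose, Sparcl1, by 0.50 (443 ± 44.5 to 625 ± 48.3 CPM, SD, n = 4), and 3 were higher adjusted over the list alone. The list had a median of 0.22 (camera adjusted p = 0.00147, adjusted p = 0.583 with an estimated correlation). The intermediate filament gene Gfap and the water channel gene Aqp4 had log2 fold changes of 0.71 and 0.85 and did not pass. Of 12 genes of the oligodendrocyte lineage 0 passed and 4 were higher adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0240, adjusted p = 0.583 with an estimated correlation). Olig1, Bcas1, Mog and Nkx2-2 had log2 fold changes of 0.59, 0.51, 0.44 and 0.50. In the layer lists, Mdga1 rose by 0.71 among 16 upper-layer genes (camera adjusted p = 0.331), with 4 higher and 3 lower adjusted over the list alone. Rorb of that list had a log2 fold change of -0.63 and did not pass over all genes (limma adjusted p = 0.113). Among 20 deep-layer genes (camera adjusted p = 0.928) Tshz2 rose, as did Ntsr1, a receptor gene of layer 6 neurons, by 0.52. The Cajal-Retzius, radial glia, subplate, interneuron, patterning, migration, axon guidance, channel, autism risk, microglia, vessel, blood, meninges, thalamus, hippocampus, immediate-early and stress lists had camera adjusted p from 0.253 to 0.992. Of these, the interneuron, patterning and immediate-early lists, and the deep-layer list, had a median and a mean of opposite sign. Without control library 1 the adjusted p was 0.0989 for astrocytes, 0.304 for the oligodendrocyte lineage, 0.0654 for intermediate progenitors and new neurons and 0.310 for the synapse list. The oligodendrocyte value was 0.0745 without cKO library 7, 0.318 with no filter and 0.134 in 1 fit over all 16 libraries.

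The P7 comparison asks which transcripts depend on Foxp1 once layers have formed and synapses are being made. Rorb, the nuclear receptor gene that marks layer 4 neurons (chromosome 19, 18930605 to 19111196), fell from 240.4 ± 16.3 to 77.3 ± 6.96 CPM (SD, n = 4, limma adjusted p = 4.8e-09), a log2 fold change of -1.63 (SE 0.07). Its paralog Rora (chromosome 9, 68653786 to 69388246) fell from 256.01 ± 4.28 to 119 ± 7.07 CPM, a log2 fold change of -1.10 (SE 0.05). The melanocortin receptor gene Mc4r (chromosome 18, 66857704 to 66860506) rose from 3.02 ± 0.353 to 11.4 ± 1.30 CPM, by 1.63 (SE 0.12). Glra3, a glycine receptor subunit gene (chromosome 8, 55940460 to 56130070), rose from 32.1 ± 3.31 to 84.9 ± 15.0 CPM, by 1.36 (SE 0.10). Rxfp2, the receptor gene of insulin-like peptide hormones (chromosome 5, 150018675 to 150082184), fell from 9.52 ± 0.8287 to 2.04 ± 0.502 CPM, a log2 fold change of -1.80 (SE 0.14).

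Among the other genes with large changes at P7, the secreted phosphoprotein gene Spp1 (chromosome 5, 104435118 to 104441050) rose from 20.01 ± 2.62 to 41.8 ± 10.9 CPM (SD, n = 4). The prostaglandin-degrading enzyme gene Hpgd rose by 1.10, the synaptotagmin gene Syt17 by 0.92, Stac by 0.91, the activin antagonist gene Fst by 0.83, Smoc2 by 0.87 and the dynein gene Dnah8 by 0.92 on the log2 scale. The predicted gene Gm765 rose by 1.11. The potassium channel gene Kcnh5 (chromosome 12, 74897220 to 75177332) fell from 64.2 ± 3.54 to 31.2 ± 6.81 CPM and the integrin gene Itgb3 (chromosome 11, 104608000 to 104670476) from 10.4 ± 0.928 to 4.37 ± 0.506 CPM. Rgs9bp, Plb1, Vgll3, Dock5 and Pld5 fell, with log2 fold changes of -1.56, -1.39, -1.18, -1.11 and -1.11. The 4 cKO values of each of these genes lay beyond all 4 control values.

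Of the 12828 genes tested at P7, limma called 477, of which 214 rose and 263 fell, and 18 changed over 2-fold. At an unadjusted p under 0.05 there were 1831 genes. The split of higher and lower genes moved with the scaling, to 155 higher and 303 lower with medians of ratios, 162 and 301 with edgeR and 215 and 389 with DESeq2. The count was 281 without control library 46 and 175 in 1 fit over all 16 libraries. Of 53 called genes chosen to be named, 28 kept their calls under every alternative that tested them. Of these, Foxp1, Dnah8 and Pld5 were not in the fit of genes without overlap, and Gm765, Rgs9bp, Plb1 and Vgll3 not in the fit with a mean of at least 5 CPM. The 28 included Rorb, Rora, Mc4r, Glra3, Rxfp2, Kcnh5 and Spp1. The other 25 lost theirs under at least 1 alternative, 14 of them without control library 46, 12 without control library 47, 8 without each of control libraries 43 and 45, 7 without each of cKO libraries 42 and 48, 6 without cKO library 41 and 5 without cKO library 44. In 1 fit over all 16 libraries 22 were lost, with no filter 14, with the striatal covariate 12, with a minimum absolute log2 fold change of 0.3 9, with medians of ratios and with quantile normalization 4 each, with edgeR and with DESeq2 3 each, and with a pseudocount of 0.1 and with a robust spread 1 each.

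**Figure D2:**
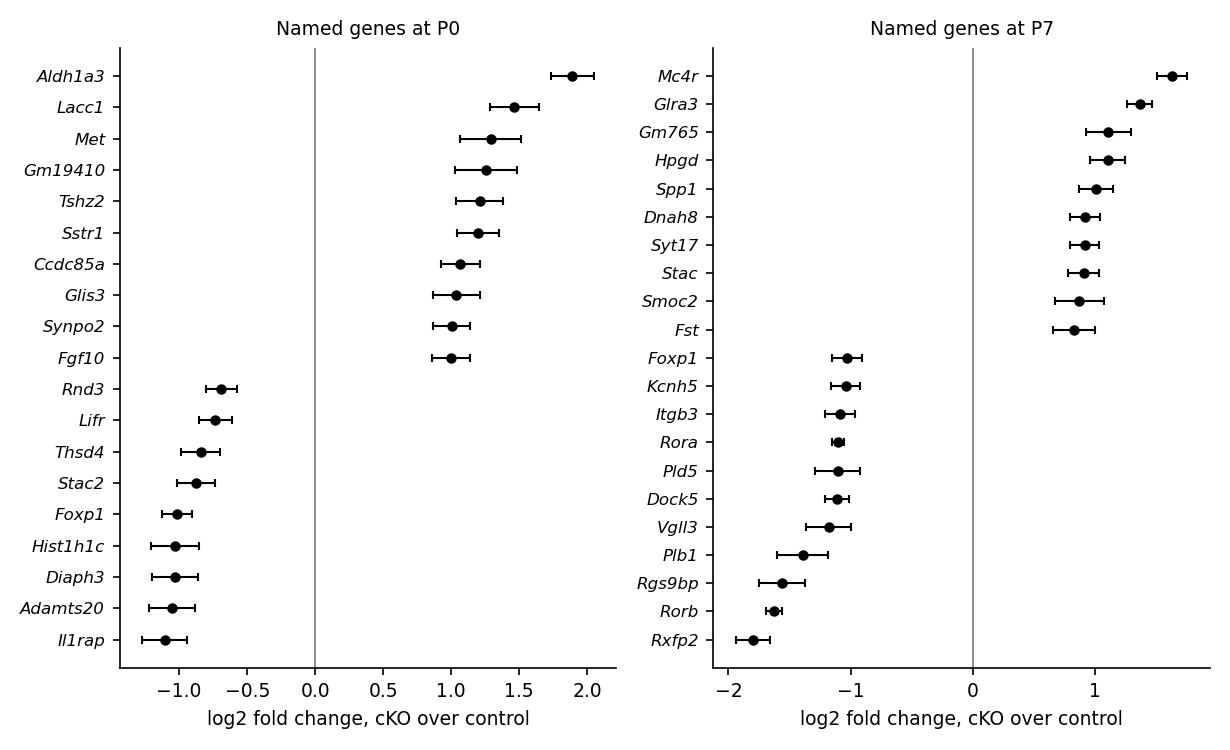
Log2 fold change (cKO over control, horizontal axis) with its standard error for the genes named by the rule at P0 and at P7, from 4 libraries per group. At P0 values run from -1.11 for Il1rap to 1.89 for Aldh1a3, and at P7 from -1.80 for Rxfp2 to 1.63 for Mc4r.

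Layer markers moved in both directions at P7. Among 20 deep-layer genes 1 rose and 4 fell, with 1 higher and 6 lower adjusted over the list alone and a median of -0.07 (camera adjusted p = 0.00833, adjusted p = 0.194 with an estimated correlation). Ntsr1 rose by 0.71, while the heparan sulfate enzyme gene Hs3st4, Rprm and Fezf2, a determinant of subcortically projecting neurons, fell, at -0.56, -0.71 and -0.35. Among 17 upper-layer genes 2 rose and 2 fell, with 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.434). Rorb and the plexin gene Plxnd1 fell, the latter with a log2 fold change of -0.57, and Lhx2 and Kitl rose by 0.26 and 0.19. Of 9 subplate genes the complexin gene Cplx3 fell, from 8.40 ± 0.314 to 4.11 ± 0.414 CPM (SD, n = 4), and Moxd1 rose by 0.52 (camera adjusted p = 0.776). Of 7 Cajal-Retzius genes Calb2 rose, by 0.73 (camera adjusted p = 0.108). In the deep-layer list the adjusted p was 0.0602 after quantile normalization and 0.101 with fry.

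Of 30 voltage-gated channel genes at P7 8 fell and 0 rose, with 10 lower and 1 higher adjusted over the list alone and a median of -0.08 (camera adjusted p = 7.9e-08, adjusted p = 0.194 with an estimated correlation, kept by fry). Beside Kcnh5, the M-current genes Kcnq3 and Kcnq5 fell, at -0.27 and -0.32. Of 33 synaptic genes 1 rose and 3 fell, with 4 higher and 7 lower adjusted over the list alone and a median of -0.06 (camera adjusted p = 0.00726, adjusted p = 0.458 with an estimated correlation). The vesicle fusion gene Snap25 fell from 1412 ± 26.1 to 1148 ± 89.5 CPM (SD, n = 4), and the kinase gene Camk2a and the NMDA receptor gene Grin2a fell, at -0.39 and -0.31, while the AMPA receptor gene Gria1 rose by 0.25. Of 36 axon guidance genes 4 rose and 3 fell, with 5 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.171). The repellent Sema3a rose from 108 ± 5.38 to 155 ± 11.2 CPM, Efnb2 rose by 0.36, and the netrin receptor gene Dcc and Plxnd1 fell, at -0.48 and -0.57. The synapse list had an adjusted p of 0.255 with fry, 0.218 after quantile normalization and 0.102 with the striatal level as a covariate, a setting chosen after the data were seen.

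Of 17 radial glia genes at P7 1 rose and 2 were higher adjusted over the list alone, with a median of 0.13 and 16 positive (camera adjusted p = 0.00244, adjusted p = 0.201 with an estimated correlation, kept by fry). The matrix gene Tnc rose from 219.5 ± 6.38 to 288 ± 12.1 CPM (SD, n = 4), and Pax6 had a log2 fold change of 0.43 and did not pass (adjusted p = 0.0543). Of 11 patterning genes 2 rose, Bhlhe22 by 0.51 and Lhx2, and 5 were higher adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0240, adjusted p = 0.201 with an estimated correlation, kept by fry). Of 11 genes of intermediate progenitors and new neurons Sox11 rose by 0.42 and Elavl2 fell, at -0.24 (camera adjusted p = 0.910). The cell cycle list had 1 of 22 members higher, Ccnd2, by 0.29 (camera adjusted p = 0.423). Of 18 migration genes Cdh4 rose by 0.68 and Cdk5r2 fell, at -0.30 (camera adjusted p = 0.581). The patterning list had an adjusted p of 0.0973 without control library 45 and 0.162 without cKO library 48.

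Striatal markers had a median of 0.33 at P7, with 14 of 15 members positive and 0 passing (camera adjusted p = 0.00784, adjusted p = 0.652 with an estimated correlation). Their mean log2 level was 4.45 ± 0.28 in cKO and 3.98 ± 0.67 in control cortex (SD, n = 4, exact permutation p = 0.229). Control library 43 had a level of 4.99, against 3.58 to 3.70 in the other controls and 4.196 to 4.78 in cKO libraries. The opioid peptide gene Penk had 19.1 ± 4.95 CPM in cKO and 10.9 ± 10.8 CPM in control cortex. The list's adjusted p was 0.110 without control library 45, 0.103 without control library 46 and 0.119 without cKO library 48. It was 0.0745 with a mean of at least 5 CPM and 0.400 with fry. With the striatal level as a covariate the direction turned (adjusted p = 0.429). That covariate is the level of the list itself, so the turn decides nothing. Among the remaining lists, single members changed in the interneuron (Npy, 0.39), astrocyte (Slc1a2, -0.27), choroid plexus (Enpp2, 0.33), meninges (Lum, -0.75) and stress (Hsph1, -0.19) lists, with camera adjusted p of 0.227, 0.612, 0.207, 0.673 and 0.910. In the thalamus list Rora fell and Calb2 rose (camera adjusted p = 0.802). The autism risk, oligodendrocyte, microglia, vessel, hippocampus and immediate-early lists had 0 passing members in limma and camera adjusted p from 0.171 to 0.910. The median and the mean had opposite signs in the subplate, new neuron, meninges and vessel lists, and in the thalamus list both were positive while camera's direction was lower.

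**Figure D3:**
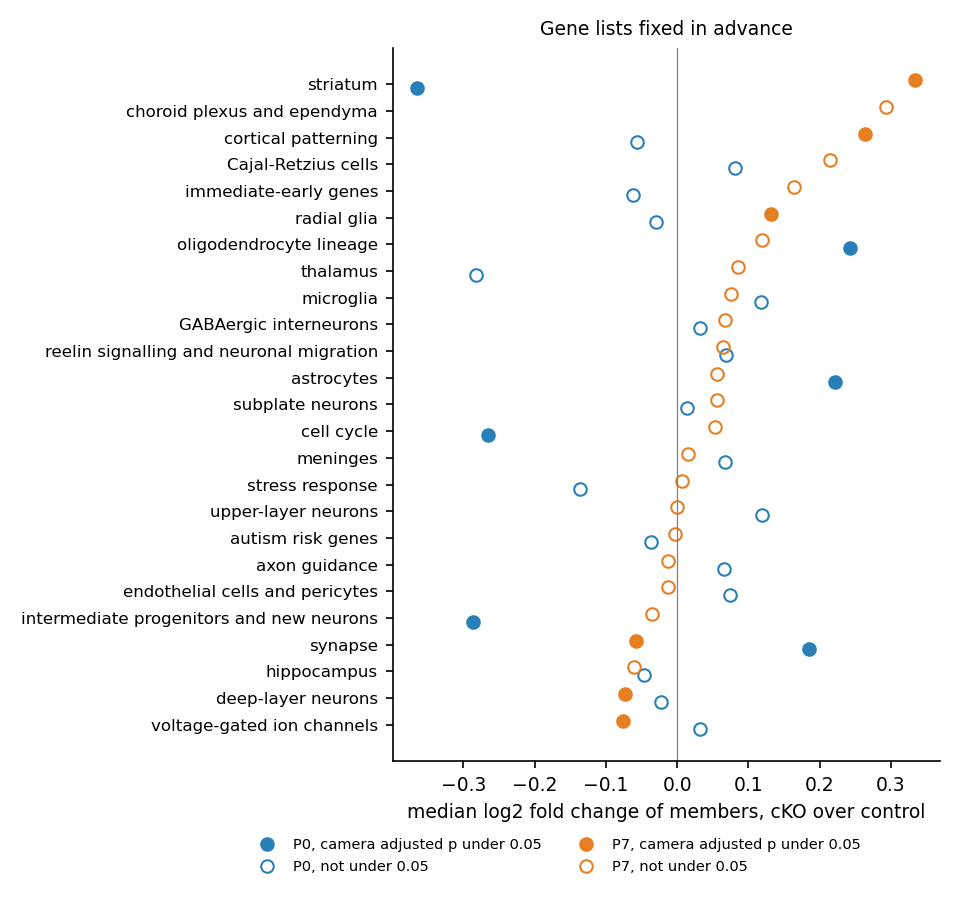
Median log2 fold change (cKO over control, horizontal axis) of the members of each gene list at P0 and at P7, with filled points where the camera adjusted p was under 0.05. Cell cycle members have a median of -0.27 at P0, and striatal markers have medians of -0.36 at P0 and 0.33 at P7.

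The overlap of the calls asks whether the same genes changed at both ages, whose libraries are all different. Among the genes that rose at P0 and at P7 were Aldh1a3, Fgf10, Glis3, Lacc1, Met and Ntsr1, and also Doc2b and Hdac9, which were chosen after their values were seen. Foxp1, Adamts20, Diaph3, Il1rap and Lifr fell at both ages. Among 12001 genes tested at both ages, 9 rose at both against 0.381 by chance (Fisher's exact p = 5.3e-11), and 5 fell at both against 0.181 by chance (Fisher's exact p = 3.8e-07). Fisher's test takes genes as independent, which they are not, so these p overstate the evidence, and the targeted gene Foxp1 is among the 5. In other splits of the P0 libraries, examined after the data were seen, up to 6 of as many P0 genes with the smallest p were called at P7, against 14 in the real split. Of the 32 genes called at P0, 27 had the same sign at P7, or 84.4%. Of the 441 genes called at P7 and tested at P0, 293 had the same sign at P0, or 66.4%. Across all genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.113 and a Spearman correlation of 0.0754. The 14 shared calls became 23 without P0 control library 1, 7 without P0 control library 6, 3 without P0 cKO library 3, 4 without P0 cKO library 4, 4 without P0 cKO library 7 and 3 without P0 cKO library 8.

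**Figure D4:**
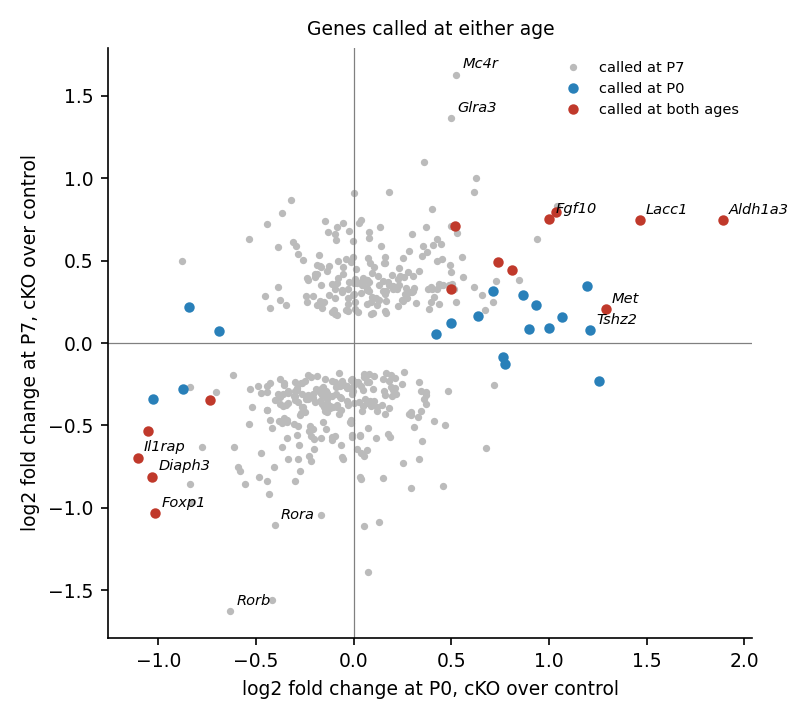
Log2 fold change (cKO over control) at P7 against that at P0 for the genes called at either age. The 14 genes called at both ages have the same sign at each age.

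The interaction asks whether the genotype effect differed between ages. Age, sequencing centre and instrument were the same split of the libraries. A genotype effect that differed with the platform therefore cannot be told apart from one that differed with age. Rxfp2 had the largest negative contrast, -2.08 (SE 0.19, limma adjusted p = 1.4e-05), with 0.332 ± 0.144 CPM in P0 control, 0.622 ± 0.183 in P0 cKO, 9.52 ± 0.8287 in P7 control and 2.04 ± 0.502 in P7 cKO cortex (SD, n = 4). Its P0 means lay below the added 1 CPM, which makes its log2 fold change at P0 smaller. Hs6st3, a heparan sulfate sulfotransferase gene (chromosome 14, 119138341 to 119869815), had 13.4 ± 0.748 and 22.5 ± 5.60 CPM at P0 and 226 ± 18.3 and 146 ± 25.2 CPM at P7, a contrast of -1.32 (SE 0.19). The imprinted gene Peg10 (chromosome 6, 4747306 to 4760517) had 53.8 ± 7.92 and 36.8 ± 6.36 CPM at P0 and 31.9 ± 4.196 and 49.9 ± 4.25 CPM at P7, a contrast of 1.17 (SE 0.18). Pax6, the radial glia transcription factor gene, had a contrast of 0.91 (SE 0.17), with 67.3 ± 10.4 and 47.4 ± 2.44 CPM at P0 and 12.6 ± 1.28 and 17.4 ± 2.53 CPM at P7. The neurofilament gene Nefm had 77.9 ± 6.75 and 112 ± 38.7 CPM at P0 and 157 ± 11.3 and 86.3 ± 14.5 CPM at P7, a contrast of -1.32, and its body overlaps that of Nefl on the opposite strand, so that its P0 value is uncertain. Positive contrasts were also called for the lysosomal reductase gene Ifi30 (1.38), the apoptosis gene Pmaip1 (1.17), Ikbke (1.17) and the monoamine transporter gene Slc18a1 (1.51), and negative ones for Gm19410 (-1.48) and Plb1 (-1.46). Foxp1 itself had a contrast of -0.02 (SE 0.19, adjusted p = 0.979).

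Of the 13444 genes in the fit over 16 libraries, 101 had a called interaction, 41 positive and 60 negative, and 2095 had an unadjusted p under 0.05. Other scalings gave 32 positive and 77 negative with medians of ratios and 31 and 72 with edgeR. The count was 207 without P0 control library 1, 361 without P0 control library 5, 45 without P0 cKO library 3, 55 without P0 cKO library 4, 66 without P7 control library 43, 48 without 45, 47 without 46, 49 without 47, 52 without P7 cKO library 41, 65 without 42 and 52 without 48. Of the 14 called genes named here, Rxfp2, Hs6st3, Peg10, Pax6, Ifi30, Pmaip1 and Gm19410 kept their calls under every alternative that tested them, which for Rxfp2 and Pmaip1 leaves out the fit with a mean of at least 5 CPM. The other 7, Slc18a1, Ikbke, Plb1, Nefm, Sox11, Grin1 and Aqp4, lost theirs under at least 1. Of these calls, 3 were lost without each of P0 cKO libraries 3 and 4, P7 control libraries 45, 46 and 47 and P7 cKO libraries 41, 42 and 48, 2 without P0 cKO library 7 and without P7 control library 43, and 1 without each of P0 control libraries 2 and 6, P0 cKO library 8 and P7 cKO library 44. With no filter and with the striatal covariate 4 each were lost, with a pseudocount of 0.1 3, with quantile normalization and with edgeR 2 each, and without P0 control libraries 2 and 6 together 1.

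The 22 cell cycle genes had a median interaction contrast of 0.40, with 0 passing over all genes (camera adjusted p = 6.1e-05, adjusted p = 0.378 with an estimated correlation). Sox11 was called among 14 genes of intermediate progenitors and new neurons, with a contrast of 0.62, and the list had a median of 0.33 (camera adjusted p = 0.0179, adjusted p = 0.378 with an estimated correlation). Pax6 was the 1 called member of 18 radial glia genes, whose median was 0.16 (camera adjusted p = 0.0179, adjusted p = 0.275 with an estimated correlation, kept by fry). Grin1, a subunit gene of NMDA receptors, had a contrast of -0.56 and was the 1 called member of 33 synaptic genes, whose median was -0.15 (camera adjusted p = 8.4e-05, adjusted p = 0.275 with an estimated correlation). The 30 channel genes had a median of -0.21 and 0 passing (camera adjusted p = 0.000434, adjusted p = 0.275 with an estimated correlation). Aqp4 was the 1 called member of 16 astrocyte genes, at -1.02, and the list had a median of -0.05 (camera adjusted p = 0.0346, adjusted p = 0.378 with an estimated correlation). Striatal markers had a median of 0.81 over 15 members and 0 passing (camera adjusted p = 0.000114, adjusted p = 0.378 with an estimated correlation). The other 19 tested lists had camera adjusted p from 0.124 to 0.988, and the Cajal-Retzius, migration, autism risk and vessel lists among them had a median and a mean of opposite sign. In the choroid plexus list both were positive while camera's direction was lower. The astrocyte call was lost without P0 control library 1 (0.255), P0 cKO libraries 3 (0.0620), 7 (0.0568) and 8 (0.0730), P7 control libraries 45 (0.0653) and 46 (0.0526) and P7 cKO library 41 (0.0846), and also with medians of ratios (0.0530), quantile normalization (0.0699), the striatal covariate (0.213) and fry (0.244). The call of intermediate progenitors and new neurons was lost without P0 control library 1 (0.234), P7 control library 45 (0.0653) and P7 cKO library 48 (0.0912), and with a mean of at least 5 CPM (0.0881), no filter (0.0605), the striatal covariate (0.119) and fry (0.162). That of striatum was lost with fry (0.244) and with the covariate (0.967), which is the level of that list and so decides nothing about it. Those of cell cycle (0.0710), synapse (0.0663) and channels (0.0663) were lost with fry, and that of radial glia without P7 cKO library 48 (0.0628).

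The last comparison sets control cortex at P7 beside control cortex at P0, where age, sequencing centre and instrument were the same split of the libraries and cannot be told apart. Synaptic genes were higher at P7, with 25 of 33 members higher and 6 lower and a median of 1.21 (camera adjusted p = 4.4e-05, adjusted p = 0.222 with an estimated correlation). Of 30 channel genes 22 were higher and 6 lower, with a median of 1.17 (camera adjusted p = 9.9e-05, adjusted p = 0.222 with an estimated correlation), and Kcnq5 rose from 61.6 ± 3.86 to 445 ± 18.6 CPM (SD, n = 4). The glutamate transporter gene Slc1a2 rose from 105.1 ± 9.80 to 2119.9 ± 132 CPM, and 10 of 16 astrocyte genes were higher and 4 lower (camera adjusted p = 0.00765, adjusted p = 0.378 with an estimated correlation). All 12 meninges genes were higher, with a median of 3.20 (camera adjusted p = 2.1e-06, adjusted p = 0.222 with an estimated correlation), among them Dcn by 5.12 and Col1a1 by 4.94. Of 22 cell cycle genes 21 were lower and 1 higher, with a median of -1.03 (camera adjusted p = 0.00193, adjusted p = 0.415 with an estimated correlation), and Mcm7 fell from 81.0 ± 12.2 to 8.48 ± 1.40 CPM. Of 14 genes of intermediate progenitors and new neurons 12 were lower and 2 higher, with a median of -2.38 (camera adjusted p = 0.00668, adjusted p = 0.378 with an estimated correlation), and Neurod2 fell from 750.4 ± 55.04 to 122 ± 17.8 CPM. Of 9 subplate genes 8 were higher and 1 lower, with a median of 1.27 (camera adjusted p = 0.0114, adjusted p = 0.222 with an estimated correlation), where Cplx3 rose by 2.25 and Nxph4 fell, at -2.95.

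Foxp1 was higher in P7 than in P0 control cortex by 0.44 on the log2 scale (SE 0.13, limma adjusted p = 0.00466). Of 13444 genes 11085 were called, 4723 higher and 6362 lower at P7, and the other 19 tested lists had camera adjusted p from 0.130 to 0.920. The median and the mean had opposite signs in the striatum and blood lists, and in the stress list both were negative while camera's direction was higher. The median log2 fold change of all genes was -0.19, and scaling by medians of ratios, which moved it to 0.03, gave 5652 higher and 5483 lower. Quantile normalization gave 5322 and 5741, edgeR 5479 and 5633 and DESeq2 5585 and 5510. The 37 genes chosen to be named for age kept their calls under every alternative that tested them. Genes that overlap another, among them Foxp1, Eid1, Fbxw7, Ankrd11 and Mcm7, were not in the fit of genes without overlap, and Cplx3 was not in the fit with a mean of at least 5 CPM. The genes with the largest lower values were Myo3a, at 13126 ± 1776 CPM at P0 and 33.0 ± 1.48 CPM at P7 (SD, n = 4), Traf3ip2, at 173 ± 9.36 and 0.482 ± 0.219 CPM, Igfbpl1, at 295 ± 41.7 and 3.70 ± 0.652 CPM, and Eps8l3, at 52.9 ± 18.1 and 0.119 ± 0.141 CPM. The cytokine gene Il4 had 51.1 ± 4.64 CPM at P0 and was listed at 0 in all 4 P7 control libraries. By the positions used here, Myo3a, Traf3ip2, Igfbpl1, Eps8l3 and Il4 overlapped no other gene of the table. Whether their P0 values reflect expression or the platform and read counting of the P0 libraries was not tested, so these contrasts are uncertain as well. The genes with the largest higher values were all listed at 0 in every P0 library. Among them were genes with 1057 ± 86.7 (Eid1), 354 ± 15.4 (Fbxw7), 297 ± 4.56 (Ankrd11) and 286 ± 6.75 (Itsn1) CPM at P7.

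Listing at 0 at P0 went with the position of a gene. Of 6868 genes with a mean of at least 20 CPM at P7, 78 were listed at 0 in all 8 P0 libraries, while 0 of 7668 genes with at least 20 CPM at P0 were listed at 0 in all 8 P7 libraries. Of the 78, 72 lay wholly under the body of a gene on the opposite strand, or 92.3%, against 1 of 6769 other genes. Eid1 lies under Shc4, Ankrd11 under Gm20388 and Fbxw7 under Gm37240. Of 502 genes wholly under an opposite-strand gene and under no same-strand gene, 95.6% were listed at 0 in all P0 libraries and 27.1% in all P7 libraries. Of 16352 genes that overlapped no other gene of the table, 16.7% and 18.3% were. Of 315 genes wholly under a same-strand gene, 96.8% were listed at 0 in all P0 libraries and 97.1% in all P7 libraries. The values at P0 of genes that share their position with another gene are therefore uncertain, and so are their age contrasts. Where the shared position is on the same strand, the values at P7 are uncertain as well.

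**Figure D5:**
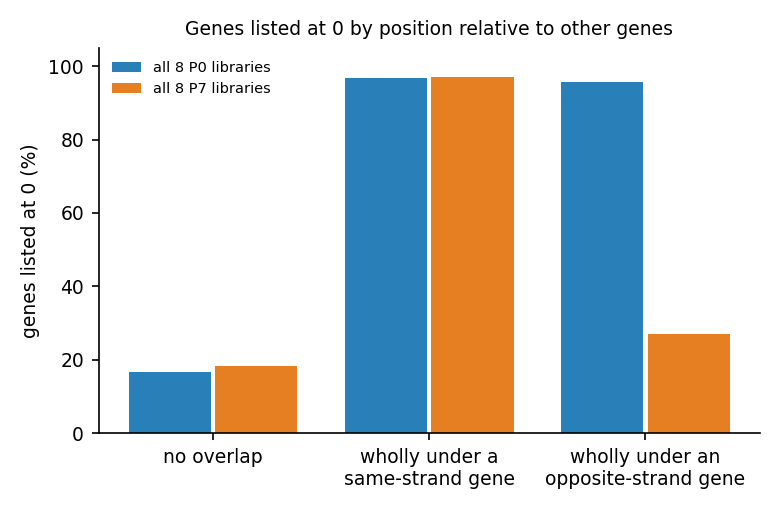
Percent of genes listed at 0 in all 8 libraries of an age (vertical axis, from 0), by the overlap of the gene body with other genes of the table. Of genes wholly under an opposite-strand gene, 95.6% are at 0 at P0 and 27.1% at P7, against 16.7% and 18.3% of genes without overlap. Of genes wholly under a same-strand gene, 96.8% are at 0 at P0 and 97.1% at P7.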

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

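Chosen only after their results were seen were the tests of opposite-strand overlap and its odds ratio, of separate sets of the P7 controls, of genes without overlap, of splits along the age axis and of the striatal members over control libraries alone.

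Listing at 0 in all P0 libraries went with 78 genes that had at least 20 CPM at P7, such as Eid1 and Fbxw7. Of these, 92.3% lay wholly under an opposite-strand gene, against 1 of 6769 other genes, which is consistent with P0 reads having been counted over whole gene bodies without regard to strand. Of the 6 others, Itsn1, Zfhx2, Fgf1, Usp2 and Camk2n2 lay wholly under opposite-strand genes when all annotated genes were searched. Whether the table holds those genes was not checked. Short reads that match several genes are argued against, since 1.28% of the 78 shared over 50% of their 50-base stretches with other genes, and so is silence of the genes at P0 as the whole cause, since the lower bound of the 95% interval of the odds ratio between listing at 0 and opposite-strand overlap was 9728. A true rise of some of these genes with age was not tested and stays open.

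At P7, 312 of the 477 called genes, or 65.4%, moved against the direction of age in control cortex, which might reflect slower maturation of cKO cortex. Control libraries shared by both contrasts stay open. With separate sets of P7 controls for each contrast, at most 34.4% of the 477 called genes went along with age. Those genes had been called with all P7 controls, so their selection rested on both sets, and this test cannot exclude shared controls. The counting at P0 also stays open. Among called genes without overlap at most 33.9% went along with age, so the pattern did not rest on genes that overlap another. Those genes too had been called with all P7 controls, and other effects of the counting or platform at P0 were not tested. Variation between libraries along the age axis stays open as well. Among as many genes with the smallest p, 14 of 35 splits of the P7 libraries, the real split included, had a majority share in 1 direction as large as the real 63.7%, and the highest other share was 83.9%. An effect of Foxp1 on maturation was not separated from such variation by these libraries.

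Within both control groups the striatal level differed between libraries, with P0 control library 2 at 3.33 against 4.34 to 4.61 in the other P0 controls. P7 control library 43 had 317 CPM of Pde10a, a member chosen after its values were seen, against 133 to 137 in the other controls. It had 305 CPM of Meis2 against 209.7 to 262. In the library with the lowest striatal level, 12 of the 15 members had at least 1 CPM. Over deviations from the group means the members had a mean pairwise correlation of 0.606, above the 95th percentile of 0.108 of random lists, which is consistent with striatal tissue in some cortex samples. Over the control libraries alone, labelled as 1 genotype, the correlation was 0.654, above the 95th percentile of 0.132 of random lists. Foxp1 genotype cannot cause differences among libraries of 1 genotype, so this test does not bear on the difference between cKO and control cortex. Whether genotype adds to that difference stays open (exact permutation p = 0.257 at P0 and 0.229 at P7).

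In 27 of 414 groups of 4 libraries, or 6.52%, 1 library lay far from the others, where chance gives about 1 in 20 groups. The ratio given is the gap to the nearest library divided by the range of the group, set against Dixon's limit for 4 libraries. P0 cKO library 3 stood apart in Aldh1a3 (12.3 CPM, others 10.5 to 10.6, ratio 0.935), Lifr (24.6 CPM, others 21.6 to 22.1, ratio 0.838), Mdga1 (280.1 CPM, others 249.8 to 255, ratio 0.837) and Pou3f3 (636 CPM, others 735 to 749, ratio 0.873). It also had a lower stress response level (5.03, others 5.12 to 5.13, ratio 0.852). P0 control library 5 was higher in Ccdc85a (39.3 CPM, others 24.4 to 26.5, ratio 0.854), Mlc1 (34.2 CPM, others 28.0 to 28.2, ratio 0.955) and Olig1 (47.1 CPM, others 30.2 to 32.6, ratio 0.861). P0 cKO library 7 was higher in Foxp4 (155 CPM, others 131 to 133, ratio 0.903) and had a lower Cajal-Retzius level (3.28, others 3.61 to 3.68, ratio 0.845). P0 cKO library 8 was lower in Cdk1 (9.46 CPM, others 12.05 to 12.3, ratio 0.897), and in P0 cKO library 4 the table held 96.4% of the library, against 96.5% in the others (ratio 0.864).

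P7 control library 43 was higher in Penk (27.1 CPM, others 4.57 to 6.15, ratio 0.930), Isl1 (3.08 CPM, others 0 to 0.205, ratio 0.933), Tac1 (12.2 CPM, others 4.05 to 5.05, ratio 0.877), Foxp2 (122 CPM, others 72.4 to 80.3, ratio 0.842) and the striatal level (4.99, others 3.58 to 3.70, ratio 0.912). P7 control library 45 was lower in Dnah8 (5.33 CPM, others 6.85 to 6.97, ratio 0.928) and in the levels of intermediate progenitors and new neurons (4.22, others 4.41 to 4.44, ratio 0.855) and of autism risk genes (8.24, others 8.26, ratio 0.870). P7 control library 47 was lower in Kl (1.25 CPM, others 2.12 to 2.25, ratio 0.869). P7 cKO library 44 was higher in Kl (2.85 CPM, others 1.04 to 1.26, ratio 0.880), Ndnf (96.5 CPM, others 73.6 to 77.0, ratio 0.849) and the Cajal-Retzius and thalamus levels (3.37, others 2.93 to 3.0, ratio 0.834, and 5.05, others 4.64 to 4.70, ratio 0.854). It was lower in Hif1a (250.5 CPM, others 262 to 263, ratio 0.883) and in the upper-layer level (6.71, others 6.88 to 6.91, ratio 0.849).

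Of 152 named genes tested, 29 had a genotype effect that differed between ages in limma, 11 with a more positive and 18 with a more negative effect at P7. Over all genes, 101 of 13444 did. Many named genes had been chosen for a large effect at 1 age or a large interaction, which raises their share. Age and sequencing platform were the same split here too. The more positive contrasts, on the log2 scale, were 1.51 for Slc18a1, 1.38 for Ifi30, 1.17 for each of Peg10, Ikbke and Pmaip1, 1.10 for Mc4r, 1.06 for Thsd4, 0.91 for Pax6, 0.90 for Stac, 0.76 for Rnd3 and 0.62 for Sox11. The more negative were -2.08 for Rxfp2, -1.48 for Gm19410, -1.46 for Plb1, -1.32 for Nefm, -1.32 for Hs6st3, -1.22 for Itgb3, -1.16 for Dock5, -1.14 for each of Aldh1a3 and Rgs9bp, and -1.13 for Tshz2. For Cplx3 the contrast was -1.04, for Aqp4 -1.02, for Rorb -0.99, for Ccdc85a -0.91, for Synpo2 -0.91, for Rora -0.70, for Hs3st4 -0.59 and for Grin1 -0.56. Among lists, the effect differed between ages for cell cycle (camera adjusted p = 6.1e-05), synapse (8.4e-05), striatum (0.000114), voltage-gated channels (0.000434), radial glia (0.0179), intermediate progenitors and new neurons (0.0179) and astrocytes (0.0346). With an estimated correlation none of these 7 lists passed.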

How the results depend on the processing

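The count tests, the striatal covariate, the fit without P0 control libraries 2 and 6 and the fit of genes without overlap were chosen after seeing the data. No paired analysis was possible because no replicate number is shared between groups. The fall of Foxp1 kept its direction, with differences of -182 to -152 CPM at P0 and -249.6 to -195 CPM at P7 when each library was left out. The counts of 32 genes at P0, 101 for the interaction and 14 shared calls became 7, 54 and 3 with no filter, where more genes are tested. They became 124, 194 and 39 with array weights, 111, 241 and 33 at an adjusted p under 0.1, 429, 285 and 70 with DESeq2, 141, 66 and 23 with the striatal covariate, and 118, 175 and 33 without P0 control libraries 2 and 6. With genes without overlap only, which are fewer, there were 27 genes at P0, 410 at P7, 83 for the interaction, 8474 for age and 11 shared calls. In 1 fit over all 16 libraries there were 794 genes at P0, 175 at P7 and 40 shared calls. Leaving out 1 library gave 4 (cKO library 3 or 8) to 136 (control library 5) genes at P0, 281 (control library 46) to 496 at P7, 45 (P0 cKO library 3) to 361 (P0 control library 5) for the interaction, 10827 to 11148 for age, and 3 (P0 cKO library 3 or 8) to 23 (P0 control library 1) shared calls. The lists called numbered 6 at P0, 6 at P7, 7 for the interaction and 7 for age. With an estimated correlation they numbered 0, 0, 0 and 0, with fry 0, 3, 1 and 25, and with 1 library left out 2 (control library 1) to 6, 4 to 8, 5 to 8, and 7. The small Foxp1 interaction contrast of -0.02 changed sign to 0.11 with quantile normalization and to 0.11 with array weights, and ran from -0.11 to 0.12 with 1 library left out, positive without P0 control library 1 (0.07), P0 cKO library 4 (0.00338) or 8 (0.05), P7 control library 43 (0.08) or 47 (0.00856) and P7 cKO library 44 (0.12). The log2 fold change of Foxp2, P7 cKO over P7 control, was near 0, became 0.10 with array weights and ran from -0.0914 to 0.16, positive without control library 43 (0.16) and cKO libraries 42 (0.00543) and 44 (0.08). With the striatal covariate the striatum list changed sign at P7 (adjusted p = 0.429) and for the interaction (adjusted p = 0.967), since the covariate is the level of that list. For the other changes the cause was not tested. The P7 and age counts stayed within 1.5 times under every other alternative run. The count tests gave no list values, because camera and fry were run on log2(CPM + 1) only. In the simulation, a 1.5-fold change was recovered for 55.2% of changed genes at P0 and for 32.8% in the interaction. Those genes had a mean of at least 5 CPM and were drawn independently, so recovery in the real fits may be lower.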

Other observations

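The 8 lists of the next 2 paragraphs, and the splits of the P0 and of the P7 libraries by number of genes called, the splits for the P0 genes with the smallest p, and the splits for the correlation and the shared signs between ages, were chosen only after the results were seen.

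Of 10 tested genes of layer 4 neurons 5 fell at P7. Beside Rorb, Rora and Kcnh5, Whrn fell (-0.67, SE 0.11) and so did Zmat4 (-0.57, SE 0.12). Of 4 tested neurofilament genes, which build the axonal skeleton of long-range neurons, 3 fell, Nefm (-0.87), Nefh (-0.64) and Nefl (-0.58). Of 19 genes for the synthesis and modification of heparan sulfate 5 fell, Hs3st2 (-0.84, SE 0.08), Hs3st4 (-0.56), Hs6st3 (-0.64), Ext1 (-0.27) and the endosulfatase gene Sulf2 (-0.37). Of 15 genes for inhibitors of Wnt signalling 6 rose, Sfrp2 (0.67, SE 0.13), Shisa3 (0.64), Nkd1 (0.46), Sfrp1 (0.39), Draxin (0.37) and Dact1 (0.33), while Dkk3 fell (-0.31). Shisa3 and Dact1 are uncertain, the former for an overlap of 34.5% of its body with Atp8a1 on the opposite strand and the latter for 33.7% of shared 50-base stretches. Values of members had been seen before these lists were written, so only counts of members are given for them and no p of a list.

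Peptide receptor genes changed in both directions at P7, with 6 of 32 tested members higher and 3 lower. Oxtr, the oxytocin receptor gene, rose by 0.60 (SE 0.12), Npr3 and Npy1r rose by 0.38 each and Prokr2 by 0.36, next to Mc4r and Ntsr1, and Glp2r fell (-0.96, SE 0.19), as did Rxfp1 (-0.50) next to Rxfp2. Of 21 cadherin genes 4 rose and 6 fell, among them Pcdh8 (0.71, SE 0.10) and Cdh13 (0.42) on the higher and Cdh12 (-0.57, SE 0.08) and Pcdh9 (-0.41) on the lower side. Of 16 neuropeptide genes Adcyap1 rose by 0.52 and Npy by 0.39, and Spx fell (-0.63). Of 16 genes of retinoic acid signalling Aldh1a3 alone passed, higher by 0.75 (SE 0.13). At P0 no member of the layer 4, neurofilament, heparan sulfate, cadherin or Wnt inhibitor lists passed in limma. Nefl, under Nefm on the opposite strand, was listed at 0 in every P0 library.

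Other splits of the same libraries show how often regrouping gave a count as large as the real one. For the genes called, only the real split did so in each comparison. At P0 it was 1 of 35 splits (32 genes, against at most 1 in another) and at P7 1 of 35 (477 against 26). For the interaction it was 1 of 100 (101 against 52). A share of 1 of 35 is the smallest that 35 splits allow, so chance is made less likely and is not excluded. For age, 1 of 35 splits reached the real count (11085 against 4), which decides nothing, because every other split mixed the ages. For the shared calls, 1 of 35 splits of the P0 libraries reached the real count (14 against 0), which decides nothing, because the other splits called at most 1 gene. Among as many P0 genes with the smallest p as were called, the real split held 14 called at P7 with the same sign and the highest other 6. There too 1 of 35 reached the real count, the smallest share that can arise. For the lists called chance cannot be excluded, and other splits often reached the real count. At P0, 9 of 35 splits called as many lists (6 in the real split, 8 in the highest other), at P7 10 of 35 (6 and 10), for the interaction 12 of 100 (7 and 10) and for age 10 of 35 (7 and 11).

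The correlation of the fold changes at P0 and P7 over 12001 genes was 0.113 by Pearson's measure, with a highest other absolute value of 0.111 over 35 splits of the P0 libraries, and 0.0754 by Spearman's, with a highest other of 0.0906. The former was reached by 1 of 35 splits, the real one, and the latter by 10 of 35. Chance is excluded for neither. It cannot be excluded for the 66.4% of P7 calls with the same sign at P0 either, where the highest other split had 69.6%.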
